A study of Homo sapiens with 115 samples.

How the data were processed

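The values were log2 expression values per probeset, deposited by the authors as one table of 115 arrays, 61 from kidney transplant biopsies and 54 from whole blood. RMA, oligo and limma are named per the submitters' processing notes, without versions or roles, and RMA is a method that corrects background, normalizes between arrays and summarises probes on the log2 scale. Whether the tissues were normalized together is not given in the sources used here. Values ran from 2.24 to 14.5, and the SD of an array ran from 1.79 to 2.14 in biopsies and from 1.96 to 2.12 in blood. Biopsy cores were freed of non-renal tissue and blood was drawn into RNA-stabilising tubes, per the labels' protocols. Between arrays the correlation reached 0.995 at most in biopsies and in blood, and no 2 arrays held identical values. The labels give separate samples, and whether every sample came from a different person is not given in the sources used here, so the p-values measure the spread between these samples.

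Of 29096 probesets, 19460 had exactly 1 gene symbol in the platform annotation, 1754 had several and 7882 had none. Through the gene identifier 19429 probesets matched RefSeq genes of GRCh38.p14, which served for names alone, and no coordinates are given because the array's build is not given in the sources used here. The 24 probesets of sex-linked genes that could show a person's sex were left out. For 768 of 18394 genes with over 1 probeset, the probeset with the highest mean in the tissue was used. Probesets whose mean lay in the lowest 25% of the named probesets of a tissue were left out, which left 13836 genes in biopsies, 13791 in blood and 13813 over both. Some genes of the lists are not analysed here, since no probeset named them alone.

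Groups were taken from the labels. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with the package data.table (version 1.17.8) for reading tables, one model of 3 group means per tissue and one of 6 group means for differences between tissues, and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Gene lists were 32, 14 of pathways and 18 of cell type markers, written from general knowledge before the data were examined. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Each list's score, the mean log2 value of its measured genes per array, was tested by a two-sided permutation test of 100000 resamples, whose smallest possible p is 1e-05, and p-values were adjusted over the 32 lists within a comparison. Limits of the simulated unchanged groups enclose 95% of them. Shares in the same direction were taken there over as many genes as limma called with all controls, those with the largest change over their SD. The standard error of a score difference comes from the SDs of both groups. Where genes are adjusted over the list alone, the adjustment covers the measured genes of that list and does not correct over the 32 lists.

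Genes named were the 8 with the largest rise and the 8 with the largest fall among called genes, the 3 members with the smallest p of each list that camera called, 1 member of each other list, and the 5 genes with the smallest p where fewer than 10 passed. A gene named for one comparison may be given in another. This rule, the groups, the tests and most alternatives were fixed before the data were examined. Unchanged groups for the shared controls were simulated by permuting residuals 1000 times, and the controls were split 100 times.

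The alternatives were no filter on dim probesets, the lower 50% left out, a further quantile normalization, array medians subtracted, array weights, a trended and robust variance, the mean of a gene's probesets, a replicate block, only the 2 groups compared, and all arrays in one model. Those for lists were camera on ranks, an estimated correlation and fry. Leaving out the 6 narrow-spread biopsy arrays (SD of values under 2) and using array SD and median as covariates in blood were chosen after seeing the data, as was the simulated share in the same direction. Scan dates and slides are not analysed here, so batches could not be tested.

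The code was tested on simulated arrays with the means and SDs of the real genes and 200 genes changed by 0.5 or 1 on the log2 scale. For biopsies with rejection against no DSA, on 13836 genes, 94% of the genes changed by 0.5 and 98% of those changed by 1 were recovered, and 4.95% of the calls were false. The false share over all 6 comparisons within a tissue ran from 3.98% to 6.93%, over 5% in all 3 blood comparisons. For DSA normal biopsies against no DSA the shares were 74% and 95%, for blood with rejection against no DSA, on 13791 genes, 87% and 100%, and for the difference between tissues, on 13813 genes, 68% and 94%. Real genes are correlated, which these simulated arrays are not. The recovered shares also hold for 200 changed genes, so they do not show how often a real change of that size would pass. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.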

Results

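Gene expression was measured on Affymetrix Human Gene 1.0 ST arrays in kidney transplant biopsies and in whole blood of transplant recipients. The recipients fell into 3 groups by donor-specific antibody (DSA), an antibody against the HLA molecules of the donor. The biopsies comprised 20 samples without DSA and with normal or near-normal histology, 13 samples with DSA and normal histology (called DSA normal here), and 28 samples with DSA and antibody-mediated rejection. The blood samples comprised 12 without DSA, 14 of the DSA normal class and 28 with DSA and rejection. Each array gave log2 values per probeset, and the median of an array lay between 6.68 and 6.87 in biopsies and between 7.04 and 7.15 in blood. Array data carry no count of molecules, so the number of arrays limits the precision. Fold changes below are log2 differences ± standard error from limma, and list scores are the mean log2 value of the measured genes of a list on each array.

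The first comparison asked which genes differed between biopsies with rejection (n = 28) and biopsies without DSA (n = 20). The chemokines CXCL11 and CXCL9, which attract T cells and are induced by interferon-gamma, rose by 2.16 ± 0.31 and 1.97 ± 0.34 in rejection, which is 4.47-fold and 3.91-fold, and the related CXCL10 rose 3.99-fold. CXCL11 and CXCL9 lay above the mean of the biopsies without DSA in 28 of 28 biopsies with rejection. GBP5, an interferon-inducible guanylate-binding protein, rose by 1.88 ± 0.30, and IDO1, the enzyme that breaks down tryptophan, rose by 1.73 ± 0.27. Of the 21 measured genes of the interferon-gamma-inducible list, 19 rose and none fell, and 19 rose when adjusted over the list alone. The score of this list was 0.96 ± 0.13 higher in rejection, with a permutation p of 1e-05, the smallest that the resamples can give, and an adjusted p of 5.3e-05.

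Antigen presentation genes rose together in rejection. Of 11 measured HLA class II genes, 10 rose, among them HLA-DPB1 by 0.82 ± 0.13, HLA-DMB by 0.77 ± 0.12 and HLA-DMA by 0.74 ± 0.11, and the same number rose when adjusted over the list alone. Of 9 measured HLA class I presentation genes, 8 rose over all genes and 8 when adjusted over the list alone, including the peptide transporter TAP1 by 0.97 ± 0.14 and the immunoproteasome subunits PSMB9 by 0.86 ± 0.13 and PSMB8 by 0.53 ± 0.08. These 2 lists share 4 and 1 genes, respectively for class I and class II, with the interferon-gamma-inducible list. Of 20 genes of the type I interferon-stimulated list, 6 rose, with 10 when adjusted over the list alone, including OAS2 by 0.80 ± 0.16 and IFI27 by 0.73 ± 0.14, and camera's call of this list was lost at adjusted p = 0.20 with an estimated correlation.

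Markers of leukocytes were higher in rejection. All 13 measured T cell genes rose, among them CD3D by 0.90 ± 0.20, CD247 by 0.69 ± 0.13 and the kinase LCK by 0.59 ± 0.10. Of 12 cytotoxic lymphocyte genes, 8 rose, with 11 when adjusted over the list alone, including NKG7 by 1.00 ± 0.18 and the pore-forming protein PRF1 by 0.87 ± 0.15. Of 9 natural killer cell genes, 5 rose both over all genes and when adjusted over the list alone, including the Fc receptor FCGR3A by 1.19 ± 0.20, KLRB1 by 0.98 ± 0.19 and GNLY by 0.92 ± 0.16. Of 17 monocyte and macrophage genes, 13 rose, with 16 when adjusted over the list alone, including CSF1R by 0.88 ± 0.14, TYROBP by 0.85 ± 0.16 and CD14 by 0.73 ± 0.15. Of 9 dendritic cell genes, 6 rose both ways, including IRF8 by 0.96 ± 0.20 and XCR1 by 0.91 ± 0.18. Of 17 complement genes, 9 rose, with 10 when adjusted over the list alone, and the examples C1QC (0.96 ± 0.22), C3AR1 (0.88 ± 0.19) and C1QA (0.85 ± 0.18) are genes that macrophages express. The complement list shares 3 genes with the monocyte and macrophage list.

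Plasma cell and B cell genes gave less certain calls. JCHAIN, the joining chain of polymeric immunoglobulins, rose by 1.65 ± 0.54, IGKC, the kappa light chain constant region, by 1.34 ± 0.40 and CD38 by 0.95 ± 0.21. Of 9 measured plasma cell and immunoglobulin genes, 5 rose, with 7 when adjusted over the list alone, and camera's call of the list was lost at adjusted p = 0.11 with an estimated correlation. Of 13 B cell genes, 2 rose, CD72 by 0.75 ± 0.15 and CD79B by 0.22 ± 0.07, with 7 when adjusted over the list alone, and the call was lost at adjusted p = 0.20 with an estimated correlation. Of 8 neutrophil genes, 3 rose, including S100A8 by 0.72 ± 0.23, and the call was lost at adjusted p = 0.21 with an estimated correlation.

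Endothelial genes were also higher in rejection. PECAM1, an adhesion molecule of endothelial cell junctions, rose by 0.62 ± 0.09, CD34 by 0.61 ± 0.09 and ICAM2 by 0.57 ± 0.09. Of 20 endothelial genes, 12 rose, with 14 when adjusted over the list alone, and the list score was 0.38 ± 0.06 higher. Of 15 measured genes of the antibody-mediated rejection-associated list, 12 rose, with 13 when adjusted over the list alone, including PLA1A, a phosphatidylserine-specific phospholipase, by 1.11 ± 0.15 and the endothelial chemokine receptor ACKR1 by 1.09 ± 0.19. This list shares 4 genes with the endothelial list and 4 with the natural killer cell list, and its score was 0.59 ± 0.07 higher in rejection.

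Some genes were lower in rejection. ALB, which encodes albumin, fell by 1.36 ± 0.37 on the log2 scale, APOH, a plasma apolipoprotein, by 1.02 ± 0.31, and the peptide gene LEAP2 by 0.65 ± 0.18. The small nucleolar RNA SNORD74 fell by 0.64 (limma adjusted p = 0.0099), so the largest falls were not all of genes for secreted proteins. Of 18 oxidative phosphorylation genes, 5 fell, with 6 when adjusted over the list alone, including the ATP synthase subunits ATP5F1A (-0.30 ± 0.07) and ATP5F1B (-0.25 ± 0.06), the list score differed by -0.13 ± 0.07, and camera's call of the list was lost at adjusted p = 0.45 with an estimated correlation. With a further quantile normalization this score difference was -0.049 and camera did not call the list (adjusted p = 0.18). None of 21 proximal tubule genes passed the threshold over all genes or when adjusted over the list alone, the water channel AQP1 standing at -0.28 ± 0.09, and the list score differed by -0.31 ± 0.28. Its camera call was lost at adjusted p = 0.80 with an estimated correlation and at adjusted p = 0.13 with a further quantile normalization. The distal nephron and collecting duct list (-0.15 ± 0.13), the podocyte list (-0.04 ± 0.09) and the kidney injury and repair list (-0.05 ± 0.12) were not called by camera or by their scores, although 1 gene of the injury list rose, ANXA1 by 0.46 ± 0.13.

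The lists of other cell types and processes gave few calls. The regulatory T cell score rose by 0.12 ± 0.05 (permutation adjusted p = 0.032) while camera did not call the list, and its member IL2RA stood at 0.48 ± 0.16, with 1 of 6 genes higher when adjusted over the list alone. Camera and the scores called none of the lists of smooth muscle and pericytes (0.01 ± 0.15), mast cells (0.12 ± 0.10), platelets (0.07 ± 0.07), glucocorticoid response (0.03 ± 0.09), adipocytes (-0.08 ± 0.15), the cell cycle (-0.01 ± 0.10), skeletal muscle (-0.19 ± 0.49) and erythroid cells (-0.04 ± 0.12). Of the platelet list SELP, an adhesion molecule that endothelial cells also carry, rose by 0.38 ± 0.12. For the podocyte, injury, cell cycle and erythroid lists the score and the median were below 0 while camera ranked the list upward, and for the platelet and smooth muscle lists the median was below 0 and the score above.

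In all, limma called 804 genes higher and 518 lower in rejection among 13836 genes tested, and 52 of the higher and 2 of the lower genes changed at least 2-fold. Camera called 20 of the 32 lists, 11 held with an estimated correlation, and the permutation test of the score called 16. Among the other called lists, extracellular matrix had 6 of 20 genes higher both over all genes and when adjusted over the list alone, TGFB1 by 0.56 ± 0.09, with the call lost at adjusted p = 0.32 with an estimated correlation. The cytosolic ribosomal protein list had 1 gene of 22 higher (RPS19 by 0.17 ± 0.06) and none when adjusted over the list alone, the immediate early and stress list had 1 gene of 12 higher both ways (IER2 by 0.20 ± 0.06), and their calls were lost at adjusted p = 0.32 and adjusted p = 0.44 with an estimated correlation. The 6 biopsy arrays whose values had an SD under 2 were 1 of the 20 biopsies without DSA and 5 of the 28 with rejection, and without those arrays 1160 genes were called higher and 586 lower. With a replicate block the split was 488 higher and 166 lower, with array medians subtracted it was 878 higher and 933 lower, with array weights it was 2006 higher and 2619 lower, and with a further quantile normalization it was 1000 higher and 483 lower, so which direction held more genes depended on the scaling and weighting.

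**Figure D1:**
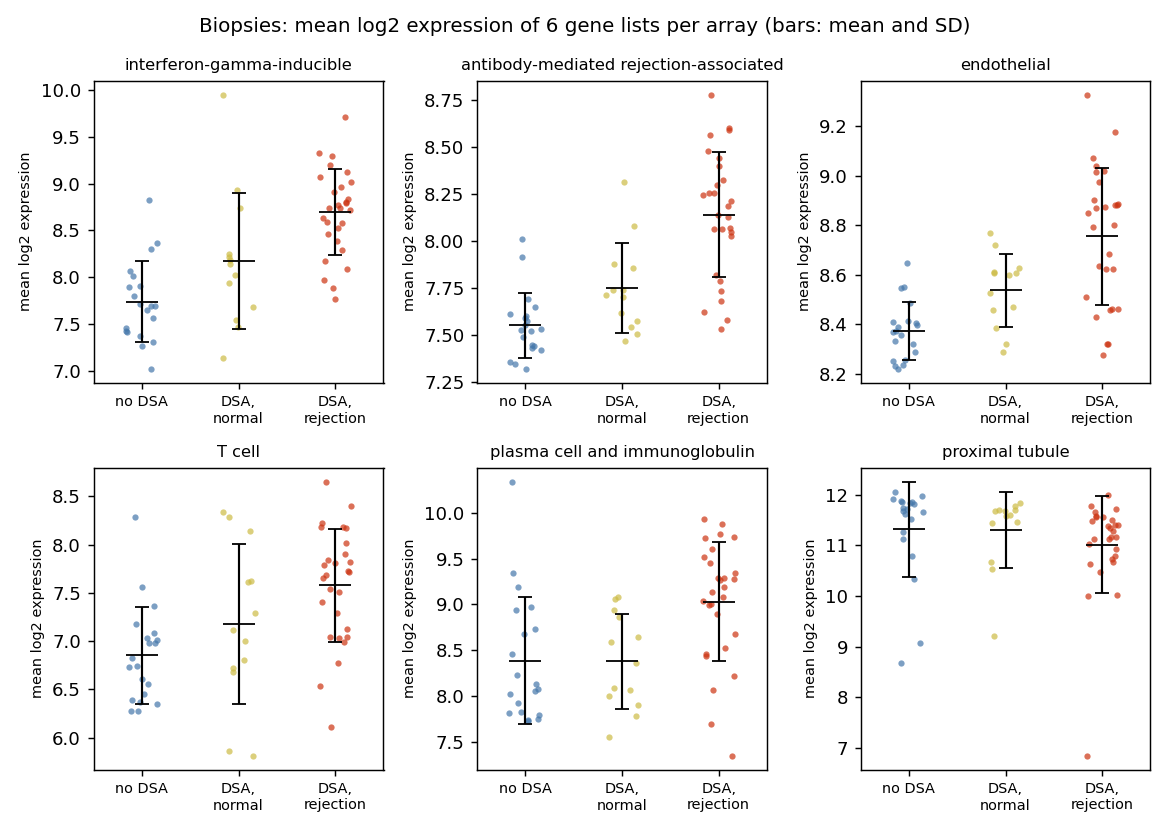
Each point is 1 biopsy array, the vertical axis is the mean log2 expression of the measured genes of the list named above the panel, and the horizontal axis gives the 3 groups (20 without DSA, 13 DSA normal, 28 with rejection), with black bars for the mean and SD. The interferon-gamma-inducible score lay above the mean of the biopsies without DSA in 28 of 28 biopsies with rejection and in 9 of 13 DSA normal biopsies, while the proximal tubule score was not called by the permutation test.

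The second comparison asked whether biopsies with DSA but normal histology (n = 13) differed from biopsies without DSA (n = 20). No single gene passed the threshold in limma, where the smallest adjusted p was 0.77. The genes with the smallest p included HLA-DMA at 0.48 ± 0.13, the kinase MAP3K8 at 0.36 ± 0.10, the cytidine deaminase APOBEC3F at 0.41 ± 0.11 (0.12 on a second probeset) and the phosphatase PTPN6 at 0.47 ± 0.13, none of which passed. The endothelial score was 0.16 ± 0.05 higher in DSA normal biopsies, with 11 of 13 biopsies above the mean of those without DSA and a permutation adjusted p of 0.049, the only list score called, while the camera call of this list was lost at adjusted p = 0.47 with an estimated correlation. Within this list CD34 stood at 0.36 ± 0.10 and the adhesion molecule SELE at 0.70 ± 0.27, and 1 of 20 genes was higher when adjusted over the list alone.

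Camera with its preset correlation called 11 lists higher and 2 lower in DSA normal biopsies, and every one of these 13 calls was lost, the smallest at adjusted p = 0.44 with an estimated correlation. The interferon-gamma-inducible score stood at 0.43 ± 0.22, the HLA class I score at 0.32 ± 0.13, the HLA class II score at 0.27 ± 0.17 and the antibody-mediated rejection-associated score at 0.20 ± 0.08. The scores of the type I interferon-stimulated (0.31 ± 0.18), monocyte and macrophage (0.33 ± 0.21), T cell (0.32 ± 0.26), dendritic cell (0.32 ± 0.17), extracellular matrix (0.19 ± 0.17) and complement lists (0.19 ± 0.16) also stood above 0 without a call by the permutation test. When adjusted over the list alone, 5 of 11 HLA class II genes, 2 of 9 HLA class I genes and 1 of 20 extracellular matrix genes were higher, besides the endothelial gene above. That adjustment does not correct over the lists, and none of these genes passed over all genes. The 2 lists called lower were skeletal muscle (-0.63 ± 0.59) and adipocyte (-0.26 ± 0.15), tissues outside the kidney. Without 1 biopsy, DSA normal replicate 1, the interferon-gamma-inducible difference was 0.29 in place of 0.43. Limma found 0 genes, against 885 at an unadjusted p under 0.05 among 13836, and limma with array weights called 286 higher and 574 lower.

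The third comparison set biopsies with rejection (n = 28) against DSA normal biopsies (n = 13). GBP7, an interferon-inducible guanylate-binding protein, was the only gene past the threshold, higher by 0.41 ± 0.08 in rejection with a limma adjusted p of 0.039, and 26 of 28 biopsies lay above the DSA normal mean. The antibody-mediated rejection-associated score rose by 0.39 ± 0.09 (permutation adjusted p = 0.015), the HLA class II score by 0.49 ± 0.16 (permutation adjusted p = 0.035) and the plasma cell and immunoglobulin score by 0.65 ± 0.19 (permutation adjusted p = 0.038). The camera call of the first list held at adjusted p = 0.012 with an estimated correlation, while those of the HLA class II and plasma cell lists were lost at adjusted p = 0.052 and adjusted p = 0.059 with an estimated correlation. When adjusted over the list alone, 9 of 15 antibody-mediated rejection-associated genes, 10 of 11 HLA class II genes and 7 of 9 plasma cell genes were higher, whereas none of them passed over all genes. Members with the smallest p were ACKR1 at 1.01 ± 0.22, PLA1A at 0.63 ± 0.18, HLA-DOB at 0.68 ± 0.20 and MZB1 at 0.70 ± 0.20.

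Camera called 18 lists higher and 1 lower in this comparison. Of these 19 calls that of the antibody-mediated rejection-associated list alone held with an estimated correlation. The endothelial list had 9 of 20 genes higher when adjusted over the list alone and a score difference of 0.22 ± 0.07, and its call was lost at adjusted p = 0.052 with an estimated correlation. The interferon-gamma-inducible list had 17 of 21 genes higher when adjusted over the list alone and a score difference of 0.52 ± 0.22, and its call was lost at adjusted p = 0.060 with an estimated correlation. The cytotoxic lymphocyte list had 6 of 12 and the natural killer cell list 4 of 9 genes higher when adjusted over the list alone, with GZMB at 0.48 ± 0.11 and PRF1 at 0.66 ± 0.17, and their calls were lost at adjusted p = 0.060 and adjusted p = 0.052 with an estimated correlation. The 11 other lists called higher included skeletal muscle (0.44 ± 0.54) and adipocyte (0.18 ± 0.15), tissues outside the kidney, and their calls were lost at adjusted p-values from 0.12 to 0.46 with an estimated correlation. The list called lower was oxidative phosphorylation (-0.16 ± 0.07), with 3 of 18 genes lower when adjusted over the list alone, lost at adjusted p = 0.40 with an estimated correlation, and with a further quantile normalization its score difference was -0.058 and the call was lost at adjusted p = 0.054. The call of GBP7 by limma was lost under 6 of the 10 alternatives that tested it. Among them was the fit without the 6 narrow-spread arrays (limma adjusted p = 0.11). An unadjusted p under 0.05 was found for 2181 of 13836 genes (15.8%). The median of an array averaged 6.78 with rejection and 6.75 in the DSA normal group (permutation adjusted p = 0.031).

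Fold changes against the biopsies without DSA were compared between the DSA normal and the rejection groups. Of the 1322 genes called in rejection, 783 were called higher there and higher in the DSA normal group, and 443 were called lower and lower in the DSA normal group, which makes 92.7% in the same direction. Both comparisons used the same 20 controls, and in unchanged groups simulated against those controls the median share in the same direction was 88.7% over as many genes, and the upper limit of the central 95% of such groups was 99.2%, so the observed share lay inside the range that shared controls alone produce. With the controls split into separate sets for the comparisons, the median share was 85.9% (40.2% to 100%) over 100 splits. It was taken over the genes called with the split controls, a median of 674.5. Unchanged groups with split controls gave a median of 57.5% and an upper limit of 89.1%, but over 1322 genes. These shares rest on unlike sets of genes and cannot be compared closely. Across 13836 genes, which are not independent replicates, the Pearson correlation was 0.63 and the Spearman correlation 0.50. Unchanged groups gave a median correlation of 0.50 and an upper limit of 0.79. The covariance was 0.0157, just above the upper limit of 0.0154 in unchanged groups. Their median was 0.00517, and the difference from that median was 0.0106. With the controls split, the correlation had a median of 0.32, from -0.09 to 0.67.

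**Figure D2:**
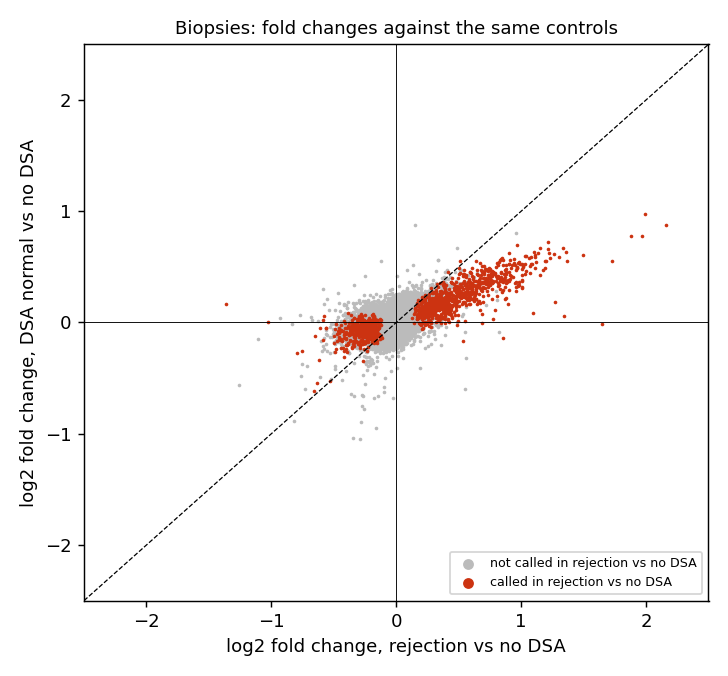
Each point is 1 of 13836 genes in biopsies, the horizontal axis is the log2 fold change of rejection against no DSA, the vertical axis is that of DSA normal against no DSA, red points are the 1322 genes called in rejection, and the dashed line marks equal changes. The red points lie mostly in the same direction on both axes (92.7%), while unchanged groups simulated against the same 20 controls had a median of 88.7% in the same direction.

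The fourth comparison asked which genes differed in blood between recipients with rejection (n = 28) and recipients without DSA (n = 12). CCR7, the chemokine receptor of naive and central memory T cells, rose by 0.87 ± 0.25, the T cell co-receptor CD4 by 0.63 ± 0.18, the tetraspanin CD151 by 0.78 ± 0.18 and the protein kinase PRKCA by 0.66 ± 0.17. The histone genes H3C2 and H3C11 fell by 0.79 ± 0.17 and 0.56 ± 0.15 on the log2 scale, and CTNNAL1, TESC and the peroxidase GPX1 fell by 0.86 ± 0.24, 0.70 ± 0.20 and 0.62 ± 0.17, although a second probeset of GPX1 stood at only -0.13. H3C2 lay below the mean of the samples without DSA in 26 of 28 samples, and CCR7 above it in 25 of 28.

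Of the 32 gene lists camera called 4 in blood, and all 4 calls were lost at adjusted p = 0.81 with an estimated correlation. Of 7 measured cell cycle genes, 1 fell, the mitotic regulator CDC20 by 0.26 ± 0.08, with 4 lower when adjusted over the list alone. Of 16 T cell genes, none passed either way, ICOS standing at 0.56 ± 0.26 and CD28 at 0.54 ± 0.25, and of 10 erythroid genes none passed, AHSP standing at -0.65 ± 0.31. Of 19 interferon-gamma-inducible genes, 1 rose, the adhesion molecule ICAM1 by 0.35 ± 0.10, with 2 when adjusted over the list alone. Camera called the cell cycle (-0.21 ± 0.08) and erythroid (-0.34 ± 0.15) lists lower and the T cell (0.36 ± 0.21) and interferon-gamma-inducible (0.19 ± 0.15) lists higher. The permutation test called none of the 32 scores, the smallest adjusted p being 0.25. Single genes of other lists that rose included CLEC10A (0.37 ± 0.09), C3 (0.41 ± 0.11), FCER1G (0.26 ± 0.07) and DNAJB1 (0.35 ± 0.09).

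Limma called 586 genes higher and 221 lower in blood among 13791 tested, and 17 of them changed at least 1.5-fold. Among 4438 probesets without a single gene name the split went the other way, with 157 higher and 520 lower. With a further quantile normalization the split was 336 higher and 273 lower, and with array medians subtracted it was 325 higher and 169 lower. The arrays themselves differed between these groups, since the SD of an array's values averaged 2.05 with rejection and 2.02 without DSA (permutation adjusted p = 0.013) and its median averaged 7.09 and 7.12 (permutation adjusted p = 0.030). With array SD and median as covariates, chosen after the data were seen, 1135 genes were called, 500 higher and 635 lower, of which 257 were among the 807.

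**Figure D3:**
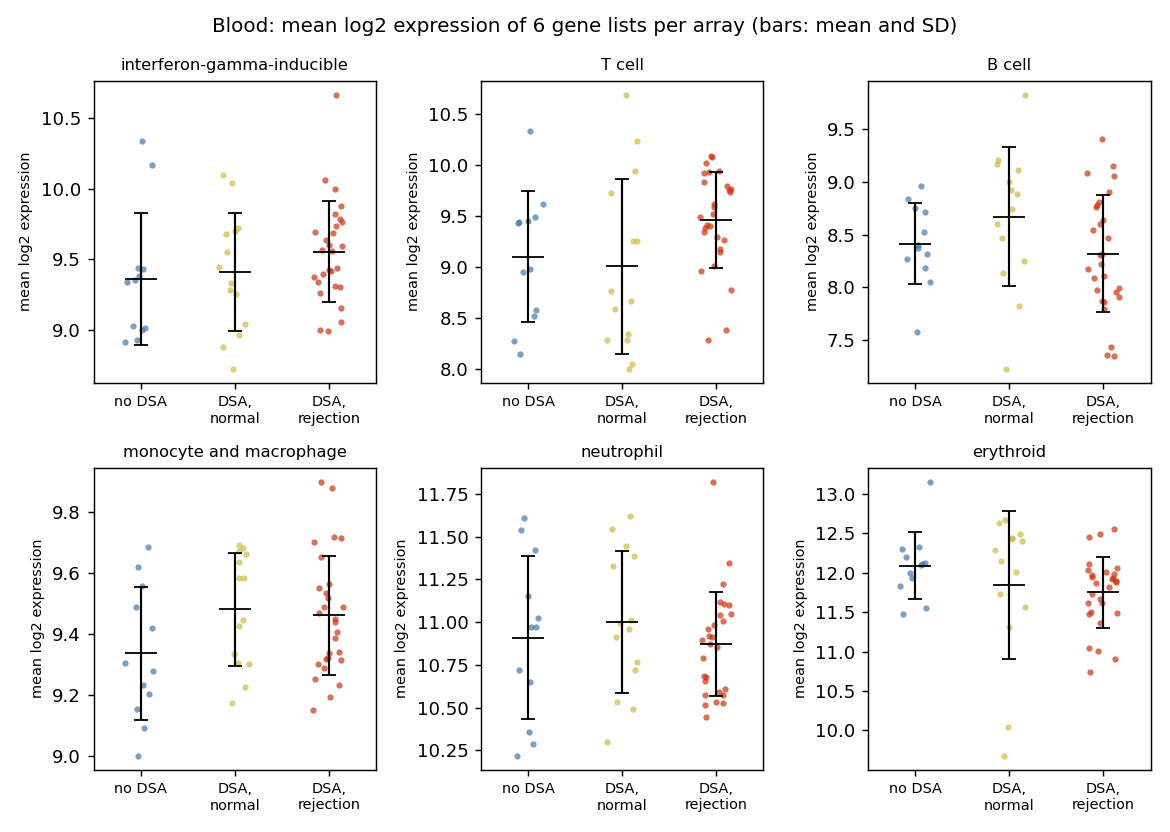
Each point is 1 blood array, the vertical axis is the mean log2 expression of the measured genes of the list named above the panel, and the horizontal axis gives the 3 groups (12 without DSA, 14 DSA normal, 28 with rejection), with black bars for the mean and SD. The groups overlap in every panel, and the permutation test called none of these scores in any of the 3 blood comparisons.

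The fifth comparison set blood of DSA normal recipients (n = 14) against blood without DSA (n = 12). NPFF, a neuropeptide precursor, was higher by 0.46 ± 0.08 with 14 of 14 samples above the mean of the samples without DSA, MILR1, a receptor of mast cells, by 0.59 ± 0.14 and the ubiquitin ligase RNF185 by 0.57 ± 0.13. CTR9, a subunit of the PAF1 transcription complex, fell by 0.36 ± 0.09 on the log2 scale, and the mitochondrial protease YME1L1 fell by 0.35 ± 0.07. Limma called 39 genes higher and 11 lower, and with only the 2 groups compared in the fit 1 gene was called, against 631 with array SD and median as covariates, 196 higher and 435 lower. The median of an array averaged 7.09 in the DSA normal group and 7.12 without DSA (permutation adjusted p = 0.031). No list was called by camera or by the permutation test, and the largest score differences were platelet (0.36 ± 0.26) and B cell (0.26 ± 0.21).

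The sixth comparison set blood with rejection (n = 28) against DSA normal blood (n = 14). No gene passed the threshold in limma under any setting run. At an unadjusted p under 0.05 stood 751 of 13791 genes (5.45%), near the share that unchanged genes would give. The T cell score stood 0.45 ± 0.25 higher in rejection (permutation p = 0.033, adjusted p = 0.29), with CD5 at 0.61 ± 0.20 and CD28 at 0.58 ± 0.24. The B cell score stood at -0.35 ± 0.20 (permutation p = 0.077, adjusted p = 0.49), with TCL1A at -0.77 ± 0.32 and FCER2 at -0.48 ± 0.19. Camera called the T cell, HLA class I, natural killer cell, interferon-gamma-inducible, ribosomal protein and oxidative phosphorylation lists higher and the B cell, cell cycle and platelet lists lower. None of the 9 calls held, and the smallest was adjusted p = 0.21 with an estimated correlation, for the cell cycle list (-0.20 ± 0.09).

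The change with rejection was then compared between biopsies and blood in one limma fit of the arrays of both tissues. The labels do not say which biopsy and blood arrays came from one patient, so all arrays were taken as independent. The difference of the log2 fold changes was 1.87 ± 0.54 for CXCL10, whose change in blood was 0.12. CXCL11 and CXCL9 were among the dim probesets left out in blood, where a change may not show, so their differences are given no rank. PLAC8 rose by 1.49 in biopsies and stood at -0.13 in blood, with a difference of 1.62 ± 0.36. CD151 stood at -0.12 in biopsies and rose by 0.78 in blood, a difference of -0.90 ± 0.20. The difference passed the threshold for 1123 of 13813 genes, with 355 differences above 0 and 768 below, whereas a further quantile normalization gave 522 and 516. For the DSA normal group the same fit called 0 genes, and array weights gave 24 above 0 and 26 below. At an unadjusted p under 0.05 stood 864 genes (6.25%), near the share that unchanged genes would give. Among 12407 genes tested in both tissues, 41 were called higher in both, where independent lists would share 35.5, and 7 were called lower in both, where they would share 6.87 (Fisher p = 0.33 and 0.85).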

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

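The differences between tissues rest on a planned test of the difference of the fold changes in one fit of all arrays, taken as independent. That test set apart 1123 genes in rejection against no DSA. Among genes tested in both tissues, the largest named differences, biopsy minus blood, were CXCL10 1.87, PLAC8 1.62, GBP5 1.60, IGKC 1.54, IDO1 1.47 and PTPRC 1.45. Those below 0 were SNORD116-21 -1.44, CD151 -0.90, DNAJC8 -0.86, PEPD -0.85, HINT2 -0.84, ZNF814 -0.84 and SNORD74 -0.80. CXCL11 (2.23), CXCL9 (1.90) and ALB (-1.32) also passed. Their probesets were among the dim ones left out in blood, where a change may not show, so they are given no rank here. In 1 of 100 splits of the arrays, the real one, as many genes passed, which is the lowest place these splits can give. The highest other split gave 610, so chance is unlikely for this count but not excluded.

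Probesets without a single gene name were outside the comparisons and also differed between groups. In biopsies with rejection against no DSA 284 of 3580 passed the threshold, in blood with rejection against no DSA 677 of 4438, and in DSA normal blood against no DSA 14 of 4438. In blood with rejection 520 of the 677 were lower and 157 higher. Of the 13791 named genes tested there 807 passed, 586 higher and 221 lower. The excess of higher genes in that comparison was therefore seen among named genes alone, and the cause was not tested.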

How the results depend on the processing

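Counts are given as called genes in total, and the cause of each change was not tested unless named. Leaving out the 6 narrow-spread arrays and using array SD and median as covariates were tests chosen after the results were seen. Biopsies with rejection against no DSA gave 1322 genes, 4625 with array weights and 654 with a replicate block. DSA normal biopsies against no DSA gave 0, and 860 with array weights. Rejection against DSA normal biopsies gave 1 gene, which became 0 with no filter, the lower 50% left out, a further quantile normalization, array medians subtracted, a replicate block, only the 2 groups compared or without the 6 narrow-spread arrays, 2162 with array weights and 60 with all arrays in one model. Blood with rejection against no DSA gave 807, 494 with array medians subtracted, 2698 with array weights and 1491 with only the 2 groups compared. DSA normal blood against no DSA gave 50, 87 with a further quantile normalization, 32 with array medians subtracted, 78 with array weights, 1 with only the 2 groups compared, 3 with all arrays in one model and 631 with array SD and median as covariates. The difference between tissues in rejection gave 1123 and 3059 with array weights, and in the DSA normal group 0, 4 with a further quantile normalization, 1 with array medians subtracted and 50 with array weights.

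Called lists moved with the assumed correlation. With an estimated correlation they went from 20 to 11 in biopsies with rejection against no DSA, 13 to 0 in DSA normal against no DSA, 19 to 1 in rejection against DSA normal, 4 to 0 in blood with rejection against no DSA and 9 to 0 in blood with rejection against DSA normal. Directional fry called 0 in DSA normal biopsies, 7 in biopsies with rejection against DSA normal, 0 in blood with rejection against no DSA and 0 in blood with rejection against DSA normal. In DSA normal blood against no DSA camera called 0, with 2 on ranks, 3 with no filter, 1 with a replicate block and, with array medians subtracted, B cell and platelet (adjusted p = 0.023 each). The correlation of the DSA normal and rejection changes was 0.63, and 0.32 with the controls split. Subtracting array medians cannot change that correlation.

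Replicate numbers gave no clear pairing of the samples and were used only in the replicate block. Deviations of same-numbered arrays had correlations from -0.37 to 0.43 between biopsies without DSA and with rejection, over 0.1 in 7 of 20 pairs, with 2 arrays correlating best with their own number. Between biopsies without DSA and DSA normal biopsies the median was 0.15 for same numbers and -0.0034 for others, over 0.1 in 9 of 13 pairs, with 3 best with their own number, so pairing there stays open, and the block results above describe a model with many terms. Single values were followed for named genes alone, each counted once per alternative, and of those of called genes 1182 kept direction and call and 139 lost the call, and of those of called lists 267 kept and 110 lost it. Of the values of named genes not called, 2698 kept direction without a call and 156 became called, 104 of those with array weights. Among the named genes not called, the sign turned for MYH7 (0.11 with a replicate block, biopsies with rejection against no DSA), RPL14 (0.0092 with a further quantile normalization, rejection against DSA normal biopsies) and, with array SD and median as covariates in blood, LEP (0.021), PODXL (0.00076) and ACTA1 (0.021) in rejection against no DSA and TNNT3 (0.0011) and LEP (0.031) in DSA normal against no DSA. With a further quantile normalization camera lost 3 of 20 calls in biopsies with rejection against no DSA, 7 of 19 in rejection against DSA normal biopsies (1 gained), 3 of 4 in blood with rejection against no DSA and 2 of 9 in blood with rejection against DSA normal. With array medians subtracted it lost 1, 3 (2 gained), 0 and 0. In DSA normal biopsies against no DSA both scalings gained 3 calls (natural killer cell, B cell and cytotoxic lymphocyte), and with array medians subtracted skeletal muscle was lost. No called list changed direction. Signal over background is not used here, and the filter on dim probesets stands in for it.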

Other observations

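The tests of narrow-spread arrays, of one DSA normal biopsy, of blood cell scores, of array SD and median as covariates and of dilution were chosen only after gene calls and array spread were seen, and bounds called set beforehand were written after that but before the tested value was computed. For splits of the arrays, 100 were counted per comparison, the real one included. No other split gave as many genes for biopsies with rejection against no DSA (1 of 100 splits, real 1322, highest other 0). The same held for blood with rejection against no DSA (1 of 100, real 807, highest other 0). It held too for DSA normal blood against no DSA (1 of 100, real 50, highest other 3). A place of 1 of 100 is the lowest these splits can give, so chance is unlikely for these counts but not excluded. The count in DSA normal blood was also unstable. It was 1 with only the 2 groups compared, 3 with all arrays in one model and 631 with array SD and median as covariates. Chance cannot be excluded for biopsies with rejection against DSA normal (5 of 100, real 1, highest other 1995). The comparisons with 0 genes were met by 100 of 100 splits, which any split must do, so that count says nothing about chance. Their highest others were 3 in DSA normal biopsies against no DSA, 1146 in blood with rejection against DSA normal and 12 for the DSA normal difference between tissues. Splits with 1995 and 1146 genes, many times the real 1 and 0, may point to structure among the arrays that the groups do not name, which was not tested, and correlated genes can also give a rare large count.

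The changes in DSA normal biopsies correlated with those in rejection. The shared controls remain open as an explanation, since with split controls the median covariance was 0.0098, below the upper limit of 0.0110 in unchanged groups. With all controls the covariance of 0.0157 lay just above the upper limit of 0.0154 in unchanged groups, while the correlation lay below its limit. For the narrow-spread arrays the criterion set beforehand was a correlation at or below the upper limit of unchanged groups without those arrays, and 0.75 against 0.78 met it. The correlation with all arrays (0.63 against 0.79) met it too, so this test decides nothing, and the correlation rose rather than fell without the arrays. One DSA normal biopsy also remains open, since the correlation was not computed with single biopsies left out. The test run used the score of the interferon-gamma-inducible list alone. Without replicate 1 that score difference was 0.657 of its value, between the bounds of 0.5 and 0.75 set beforehand. A score of 1 list cannot decide the question for the correlation across all genes.

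The genes called in blood between rejection and no DSA could come from cell proportions or from array spread, and neither can be told apart from a change within cells here. With the scores of 7 blood cell lists as covariates the median ratio of fold changes was 0.664, and 198 of the 807 genes were still called. With array SD and median as covariates the median ratio was 0.635, and 257 of the 807 were still called. Both ratios lie between the bounds of 0.5 and 0.75 set beforehand, and the array SD and median differed between the groups themselves. A change within blood cells stays untested.

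For the genes called in biopsies between rejection and no DSA, the narrow-spread arrays are an unlikely source, since without them the median ratio of fold changes was 1.04 and 1134 of 1320 genes were still called. For the genes that were lower, dilution of graft RNA by infiltrating cells remains open. The largest gap between changes of the proximal tubule, distal nephron, podocyte and endothelial lists was 4.28 standard errors, for podocyte against endothelial, which goes against an equal fall of all 4. The endothelial rise may be a change of its own, and among the other 3 lists the largest gap was 1.12 standard errors, so an equal fall of those lists cannot be ruled out. A lower expression within tubule cells was not tested apart from their share.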
